A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

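The deposited table held counts per gene for 24 libraries, and per the submitters' processing notes the authors had checked the reads with FastQC, aligned them with STAR 2.7.2a to build R64 and counted them per gene with HTSeq. The strand setting of the counting is not given in the sources used here. Per the labels the libraries came from total RNA, prepared with a stranded mRNA kit. No reads were aligned or counted again here. The 5 summary rows that name no gene were taken out before testing. Of the assigned, no-feature and ambiguous reads together, reads in no feature made up 4.39 to 6.51% and ambiguous reads 0.787 to 1.01% per library. The table held 7127 features, 6600 of them mRNA features, of which 5917 matched the reference gene table by systematic name and 683 did not.

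Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered by edgeR's rule on counts per group, libraries were scaled by TMM factors, and a negative binomial model with 1 mean per group was fitted over all 24 libraries, with robust estimation. Each of 19 comparisons was tested by the quasi-likelihood F-test with Benjamini-Hochberg adjustment over the 6518 genes tested, at 0.05 and with no minimum fold. The common biological coefficient of variation was 5.26%, with 16 residual degrees of freedom. Temperature responses were compared by the interaction contrast. The NPL3 level was also tested by an exact two-sided permutation test of log2 CPM (counts per 1e6 of the library size scaled by TMM factors).

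Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, against all genes tested and with Benjamini-Hochberg adjustment over the 34 lists in each comparison. Camera with the correlation estimated from the data and the rotation test fry were run beside it. Of the lists, 26 were written by hand from known functions, with 949 genes, 1 of which matched no feature (the name of a gene that makes 2 enzymes). The 34 lists cover phosphate starvation, cytosolic ribosomal proteins (all, with an intron and without), ribosome biogenesis, translation factors, mRNP assembly and export, splicing, 3-prime end processing, RNA polymerase II and elongation, the nuclear exosome, genes with an intron outside the ribosomal proteins (by annotation and by hand), snoRNAs, heat shock (Hsf1), general stress (Msn2 and Msn4), the proteasome, cell wall integrity, amino acid synthesis, glycolysis, the TCA cycle, the respiratory chain, glucose repression, iron, ergosterol, DNA damage, core histones, meiosis, a-cell and alpha-cell genes, retrotransposons, mitochondrially encoded genes, strain markers and mRNA features that the reference does not hold. The retrotransposon list was corrected after values had been seen, by leaving out pseudogenes. Another 4 lists were chosen after the data were seen and adjusted among themselves in each comparison. Of these, Zap1 zinc genes, sulfate assimilation and methionine genes, and genes of vitamins B6 and B1 are described. The remaining list is not reported here, nor are some of the genes that the naming rule picked, mostly list members.

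Genes were picked for naming by a fixed rule. In each comparison of a mutant with NPL3 and in the response of NPL3 to the shift these were NPL3, the 6 largest rises and the 6 largest falls, and 2 members of each list that passed. In each interaction they were the 4 largest each way, and between mutants the 3 largest each way. The largest changes were taken among protein-coding genes with a standard name, an adjusted p under the threshold, a mean of at least 10 CPM and no overlap between the replicate values of the groups, leaving out retrotransposon and strain marker genes. Near-identical copies of at least 95% identity over at least 100 bases were searched with BLAST 2.17.0 among 6008 coding sequences. Of 162 named genes, 14 had such a copy and 10 overlapped another gene.

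The overlap between mutants was set beside the value for independent lists and beside 20 simulations of unchanged mutants that shared the NPL3 libraries. Other settings were RLE size factors, no filter on low counts, a minimum mean of 10 CPM, an adjusted p of 0.01 or a change of at least 2-fold for the overlap, DESeq2 1.42.0, fits of only the groups compared, replicate number as a block (over all libraries or within each temperature), each library left out in turn, and a fit without the 4 libraries of the other sample number series. That series as a term of the fit was added after the data were seen. Whether the replicate numbers pair libraries was checked by correlating the residuals of libraries with the same number, from the data and not the labels. Only npl3-F162Y and NPL3 at 37 °C had every pair above 0.1 (r = 0.2097, 0.5456 and 0.2814 across genes, which are not independent replicates). Unlike numbers 1 and 3 of these groups also correlated (r = 0.19 and 0.1286), and 7 of 24 libraries correlated best with a library of the same number. At 30 °C none of 18 same-numbered pairs was above 0.1. Between strains at 37 °C all 6 pairs of replicate 2, the other sample number series, had r from 0.3439 to 0.5456. The remaining 12 same-numbered pairs there had r from 0.0103 to 0.3666. For each comparison all 10 splits of its 6 libraries were refitted, and for each interaction 100 splits drawn with a fixed seed.

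The tests were run on simulated data before the real data. For npl3-F162Y against NPL3 at 30 °C, with 6447 genes, edgeR recovered 92% of 50 planted genes at a fold of 1.5, 98% at a fold of 2 and 100% at a fold of 4, and 9 of its 215 calls (4.19%) were unchanged genes. DESeq2 recovered 90%, 98% and 100%, with 12 of 220 calls (5.45%) unchanged. For the npl3-F162Y interaction edgeR recovered 92%, 98% and 100% at the same folds. A planted list of 30 genes had a camera adjusted p = 1.14e-10, and of 20 random lists 0 were called by camera. The simulated genes varied independently and the random lists held only unchanged genes. That outcome therefore does not show how camera at the preset correlation treats lists of genes that vary together.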

Results

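Transcript levels were measured by sequencing of mRNA from W303 budding yeast that carried NPL3 on a low-copy LEU2 plasmid. The strains are shuffle strains, in which the plasmid copy stands in for the chromosomal gene. Npl3 is an SR-like RNA-binding protein that joins the nascent mRNA and takes part in mRNA processing and export. The plasmid held wild-type NPL3 or a mutant allele, and the mutations lie in the first RNA recognition motif (npl3-F162Y), in the linker that follows it (npl3-P196D-A197D) or in the second motif (npl3-F245I). Mid-log cultures in rich medium were kept at 30 °C or shifted to 37 °C for 1 hour, and each of the 8 groups had 3 libraries, 24 in total. The series asks how Npl3 passes the components of the messenger ribonucleoprotein from the site of transcription to the mRNA. Each mutant was therefore compared with NPL3 at each temperature, 37 °C with 30 °C in each strain, and the mutants with each other.

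Counts assigned to genes ranged from 15.8 to 34.7 M (mega) per library, with a median of 24.9 M. The group means at 30 °C were 28.7 ± 4.68 M in NPL3, 24.4 ± 2.93 M in npl3-F162Y, 19.2 ± 3.30 M in npl3-P196D-A197D and 26.1 ± 2.77 M in npl3-F245I (SD, n = 3). At 37 °C they were 28.3 ± 2.69, 24.9 ± 2.63, 24.8 ± 8.31 and 27.0 ± 7.31 M in the same order. Of 7127 annotated features, 6518 had enough counts to be tested. Pearson's r of log2 CPM (counts scaled to library size) between libraries of the same group lay between 0.9935 and 0.9975, taken across genes, which are not independent replicates. The NPL3 libraries at 37 °C were less alike than those of the other groups: replicate 1 scored 1.29 on the first principal component and the other replicates 11.2 and 11.4. The 4 libraries of replicate 2 at 37 °C carry sample numbers of another series than the rest, so counts at 37 °C are also given without them. The main fit holds no term for that series. When it was added as a term, after the data were seen, 1448 of 6518 genes passed edgeR's test for the series. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

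The NPL3 transcript itself (chromosome IV, 1328783 to 1330027, build R64) was present in every strain. At 30 °C it stood at 204 ± 5.20 CPM in NPL3, 272 ± 17.2 CPM in npl3-F162Y, 330 ± 6.47 CPM in npl3-P196D-A197D and 212 ± 5.74 CPM in npl3-F245I (mean ± SD, n = 3). At 37 °C it stood at 192 ± 11.4, 255 ± 24.0, 299 ± 21.3 and 342 ± 3.84 CPM in the same order. Against NPL3 at 30 °C the transcript was 1.34-fold higher in npl3-F162Y and 1.62-fold higher in npl3-P196D-A197D, and 1.04-fold higher in npl3-F245I, which did not pass the test (adjusted p = 0.425, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At 37 °C the folds were 1.33, 1.56 and 1.78. In npl3-F245I the transcript rose 1.61-fold with the shift to 37 °C, while in NPL3 its log2 change was -0.08 (adjusted p = 0.217 in the same edgeR test). The exact two-sided permutation test gave p = 0.1 for each of these mutants against NPL3 except npl3-F245I at 30 °C, where p = 0.2, and 0.1 is the smallest value that 3 against 3 libraries allow.

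The first comparison asks what the substitution in the first RNA recognition motif changes at 30 °C. In npl3-F162Y PHO5, a secreted acid phosphatase (chromosome II, 429548 to 430951), went from 33.2 ± 3.42 to 787 ± 31.7 CPM, a 23.6-fold rise (mean ± SD, n = 3). PHO84, the high-affinity phosphate transporter (chromosome XIII, 24037 to 25800), rose 22.3-fold, and PHO89, a sodium-coupled phosphate transporter (chromosome II, 796798 to 798522), rose 18.7-fold. PHO84 overlaps a gene on the other strand, and the counting strand was not stated. SPL2, which lowers uptake by low-affinity phosphate transporters (chromosome VIII, 374654 to 375100), rose 20.4-fold from 2.49 ± 0.104 to 50.9 ± 0.909 CPM. SNO1 of vitamin B6 synthesis rose 15.2-fold and the short open reading frame DPA10 19.4-fold. Among the largest falls were the transcription factor gene RGM1 (2.86-fold lower), the adenine deaminase gene AAH1 (2.72-fold lower), EFM3 (2.64-fold lower), SLI1 (2.53-fold lower), PRY1 (2.48-fold lower) and NCA3 (2.41-fold lower).

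By fixed lists, 18 of 19 phosphate starvation genes rose in npl3-F162Y, and 19 did adjusted over the list alone (camera adjusted p = 1.61e-48, adjusted p = 6.07e-07 with an estimated correlation). Of 137 cytosolic ribosomal protein genes 134 fell and none rose, 135 adjusted over the list alone, with a median log2 change of -0.45 (camera adjusted p = 1.72e-19, adjusted p = 0.477 with an estimated correlation). Genes with an intron (89 of 89 lower, median -0.48) and without (45 of 48 lower, median -0.41) each had adjusted p = 0.477 with an estimated correlation. RPL27B was 1.76-fold lower and RPL8A 2.16-fold lower, the latter sharing reads with its near-identical copy RPL8B. Of 105 ribosome biogenesis genes 66 fell and 5 rose, 66 and 5 adjusted over the list alone (camera adjusted p = 0.0427, adjusted p = 0.959 with an estimated correlation). Their call ended without the 4 libraries of the other number series and with replicate number as a block (adjusted p = 0.121 and adjusted p = 0.0505), as did that of the iron regulon (adjusted p = 0.0512 and adjusted p = 0.0503), in which 16 of 28 genes rose, LSO1 6.22-fold (camera adjusted p = 0.0496, adjusted p = 0.477 with an estimated correlation). Of 41 translation factor genes 33 fell, TIF35 by 0.48 on the log2 scale (camera adjusted p = 0.00778, adjusted p = 0.793 with an estimated correlation).

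Genes of other programmes rose in the same cells. Of 31 meiosis and sporulation genes 26 rose, the septin gene SPR3 by 3.07-fold (camera adjusted p = 4.98e-07, adjusted p = 0.0475 with an estimated correlation). Of 33 cell wall integrity genes 23 rose, BAG7 5.09-fold and TIR1 4.13-fold (camera adjusted p = 4.42e-10, adjusted p = 0.0491 with an estimated correlation). Of 38 glucose-repressed genes 28 rose, among them the mitochondrial succinate-fumarate carrier gene SFC1 by 5.55-fold (camera adjusted p = 1.92e-06, adjusted p = 0.177 with an estimated correlation). Of 76 snoRNA genes 41 rose and 8 fell, SNR13 from 2.63 ± 0.0996 to 9.34 ± 1.32 CPM (camera adjusted p = 0.0137, adjusted p = 0.743 with an estimated correlation). The amino acid synthesis list split into 31 higher and 19 lower of 72, with LEU1 up 2.52-fold (camera adjusted p = 0.025, adjusted p = 0.809 with an estimated correlation). Nuclear-encoded respiratory chain genes fell (29 of 35, COX4 1.58-fold lower, camera adjusted p = 0.000475, adjusted p = 0.477 with an estimated correlation). So did 18 of 26 ergosterol synthesis genes, ERG5 by 0.51 on the log2 scale (camera adjusted p = 0.0244, adjusted p = 0.616 with an estimated correlation). Of 15 a-cell and mating genes 8 fell, the a-factor gene MFA2 2.37-fold lower and the pheromone receptor gene STE2 1.65-fold lower (camera adjusted p = 0.041, adjusted p = 0.477 with an estimated correlation). Of 493 mRNA features that the reference does not hold, 175 rose and 35 fell (camera adjusted p = 0.0207, adjusted p = 0.594 with an estimated correlation). In all, 4458 of 6518 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1942 higher and 2516 lower, and 485 of them changed at least 2-fold, 424 higher and 61 lower.

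The same question for the linker mutant gave a similar set of leading genes. In npl3-P196D-A197D at 30 °C PHO84 rose 26.0-fold to 2076 ± 24.4 CPM, PHO5 23.6-fold, SPL2 20.4-fold, SNO1 12.3-fold and DPA10 11.6-fold (n = 3). PHO11, an acid phosphatase gene that shares reads with its near-identical copy PHO12, rose 12.6-fold. CHA1, the catabolic serine and threonine deaminase (chromosome III, 15798 to 16880), fell from 157 ± 8 to 55.0 ± 1.42 CPM and was 2.86-fold lower (adjusted p = 9.06e-18, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). RGM1 was 2.33-fold lower, SLI1 2.08-fold lower, AAH1 2.05-fold lower, MFA2 1.93-fold lower and GFD2 1.91-fold lower. Of the phosphate starvation genes 17 of 19 rose, 17 adjusted over the list alone (camera adjusted p = 2.28e-86, adjusted p = 1.58e-08 with an estimated correlation). Of the ribosomal protein genes 125 of 137 fell, 126 adjusted over the list alone, with a median log2 change of -0.31 (camera adjusted p = 3.41e-17, adjusted p = 0.499 with an estimated correlation). Amino acid synthesis genes rose more widely than they fell, 51 of 72 against 4, with SER3 up 2.39-fold and LEU1 2.21-fold, SER3 overlapping a transcript on its own strand (camera adjusted p = 1.69e-18, adjusted p = 0.0756 with an estimated correlation).

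Cell wall integrity genes rose in npl3-P196D-A197D as well, 22 of 33, with the cell wall protein gene PIR3 up 3.22-fold (camera adjusted p = 1.05e-11, adjusted p = 0.0412 with an estimated correlation). Meiosis and sporulation genes rose in 21 of 31 cases, the kinase gene SPS1 2.49-fold (camera adjusted p = 4.34e-05, adjusted p = 0.0756 with an estimated correlation). Of 46 retrotransposon genes 26 rose and none fell (camera adjusted p = 0.000177, adjusted p = 0.545 with an estimated correlation). These share reads among near-identical copies, and the call for YFL002W-A ended without replicate 3 of the mutant (adjusted p = 0.0503, edgeR). Glucose-repressed genes rose in 23 of 38 cases, the acyl-CoA oxidase gene POX1 3.55-fold (camera adjusted p = 7.33e-06, adjusted p = 0.181 with an estimated correlation). Translation factor genes fell in 29 of 41 cases, DED1 by 0.46 on the log2 scale (camera adjusted p = 0.00234, adjusted p = 0.704 with an estimated correlation). Of the ribosome biogenesis genes 64 of 105 fell (camera adjusted p = 0.0012, adjusted p = 0.957 with an estimated correlation), and of the snoRNA genes 18 rose and 10 fell, which did not pass (camera adjusted p = 0.673). In edgeR's quasi-likelihood test 3631 genes changed, 1568 higher and 2063 lower, 235 of them at least 2-fold.

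In npl3-F245I at 30 °C, the mutant of the second motif, PHO84 rose 15.4-fold to 1228 ± 75.8 CPM, PHO5 12.6-fold, SPL2 10.1-fold and DPA10 9.825-fold. The vitamin B6 genes SNO1 and SNZ1, neighbours on chromosome XIII (457285 to 457959 and 458408 to 459301), rose 13.8-fold and 10.2-fold, SNZ1 from 39.3 ± 0.954 to 401 ± 5.57 CPM (n = 3). HXK1, a hexokinase induced outside of glucose growth, was 3.32-fold lower, the glycerol-3-phosphate dehydrogenase gene GPD1 2.64-fold lower, RTC3 2.76-fold lower, YRO2 2.68-fold lower, RSB1 2.50-fold lower and CHA1 2.87-fold lower. Of 51 general stress genes of the Msn2 and Msn4 regulon 31 fell and 6 rose, with a median log2 change of -0.36 (camera adjusted p = 0.000835, adjusted p = 0.834 with an estimated correlation). Phosphate starvation genes rose in 17 of 19 cases, 17 adjusted over the list alone (camera adjusted p = 6.65e-36, adjusted p = 9.12e-06 with an estimated correlation). Ribosomal protein genes fell in 128 of 137 cases, 130 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 4.94e-16, adjusted p = 0.455 with an estimated correlation).

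Further groups moved in npl3-F245I at 30 °C. Meiosis and sporulation genes rose in 24 of 31 cases, the synaptonemal complex gene ZIP1 2.73-fold (camera adjusted p = 1.41e-07, adjusted p = 0.0244 with an estimated correlation). Respiratory chain genes fell in 31 of 35 cases, COX4 1.66-fold lower (camera adjusted p = 2.6e-08, adjusted p = 0.155 with an estimated correlation). Of 76 snoRNA genes 39 rose and 5 fell, SNR8 from 2.88 ± 0.306 to 9.60 ± 0.978 CPM (camera adjusted p = 0.000122, adjusted p = 0.455 with an estimated correlation). Cell wall integrity genes rose in 23 of 33 cases, the glucan synthase gene GSC2 2.65-fold (camera adjusted p = 3.05e-07, adjusted p = 0.155 with an estimated correlation). Of 15 a-cell genes 9 fell, MFA1 1.97-fold lower, while 3 of 4 alpha-cell genes rose, SAG1 1.82-fold (camera adjusted p = 0.000835 and 0.0189, adjusted p = 0.155 and 0.31 with an estimated correlation). Retrotransposon genes rose in 23 of 46 cases (camera adjusted p = 0.000122, adjusted p = 0.521 with an estimated correlation). In edgeR's quasi-likelihood test 3764 genes changed, 1595 higher and 2169 lower, 354 of them at least 2-fold.

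**Figure D1:**
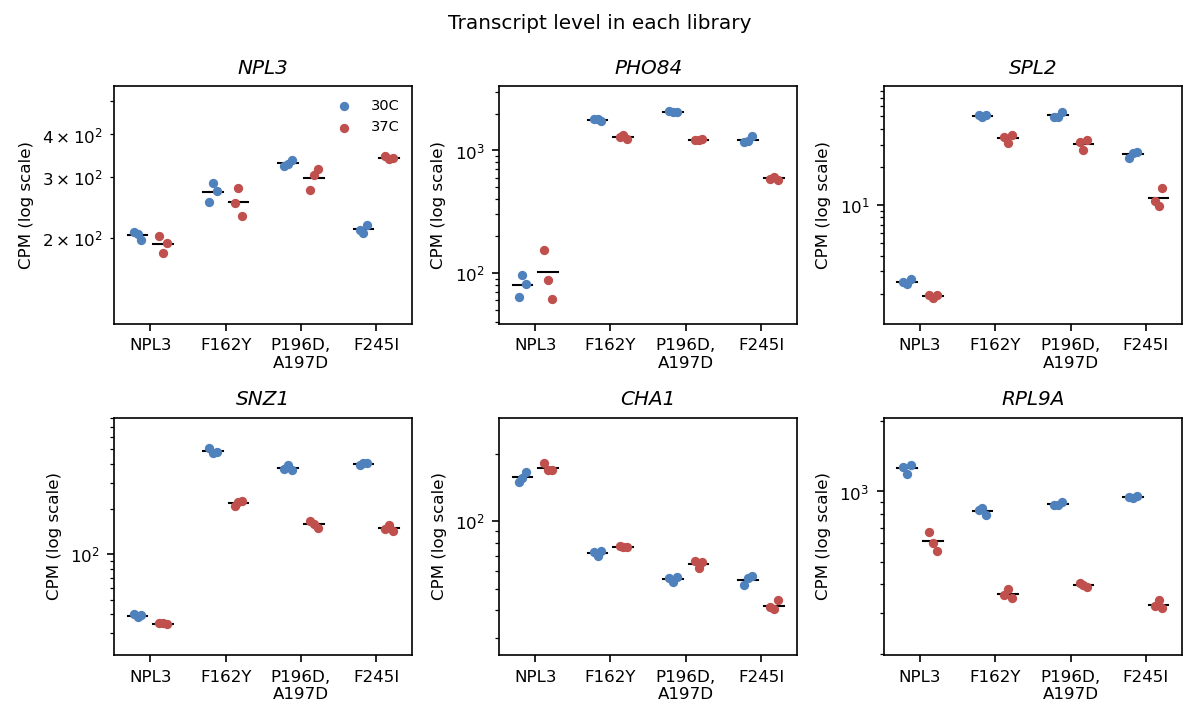
CPM (log axis) of NPL3, PHO84, SPL2, SNZ1, CHA1 and RPL9A in each of the 24 libraries, grouped by strain, with points for single libraries (30 °C in blue, 37 °C in red) and a black line at the mean of each group. At 30 °C the 3 mutant means of PHO84 (1780, 2076 and 1228 CPM) all lie above the NPL3 mean of 80.2 CPM, and those of CHA1 (72.1, 55.0 and 54.7 CPM) below its 157 CPM.

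Several gene lists close to the known roles of Npl3 did not pass camera against all other genes in npl3-F162Y at 30 °C, although many members changed. Of 34 genes of mRNP assembly and export, 7 rose and 18 fell in npl3-F162Y, 6 and 16 in npl3-P196D-A197D, and 6 and 16 in npl3-F245I (camera adjusted p = 0.854, 0.781 and 0.549). Of 81 splicing factor genes 23 rose and 26 fell in npl3-F162Y (camera adjusted p = 0.979). The genes with introns outside the ribosomal proteins split into 38 higher and 81 lower of 178 by the annotation and 28 higher and 52 lower of 114 by a hand list (camera adjusted p = 0.693 and 0.854, npl3-F162Y). Of 26 genes of 3-prime end processing and termination 9 rose and 9 fell (camera adjusted p = 0.5), of 29 genes of RNA polymerase II and elongation 8 rose and 11 fell (0.854), and of 17 nuclear exosome genes 2 rose and 11 fell (0.224) in the same mutant. Proteasome genes (7 higher and 9 lower of 35), DNA damage genes (9 and 6 of 20), core histones (0 and 2 of 8), glycolysis genes (1 and 10 of 17), genes of the TCA and glyoxylate cycles (7 and 12 of 24) and strain marker genes (3 and 3 of 6) did not pass there either, with adjusted p from 0.308 to 0.854. Hsf1 chaperone genes did not pass (7 higher and 6 lower of 31, camera adjusted p = 0.854), nor did the 4 mitochondrially encoded genes, none of which passed in npl3-F162Y. Mitochondrially encoded features held only 0.0001 to 0.0022% of the assigned counts per library.

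**Figure D2:**
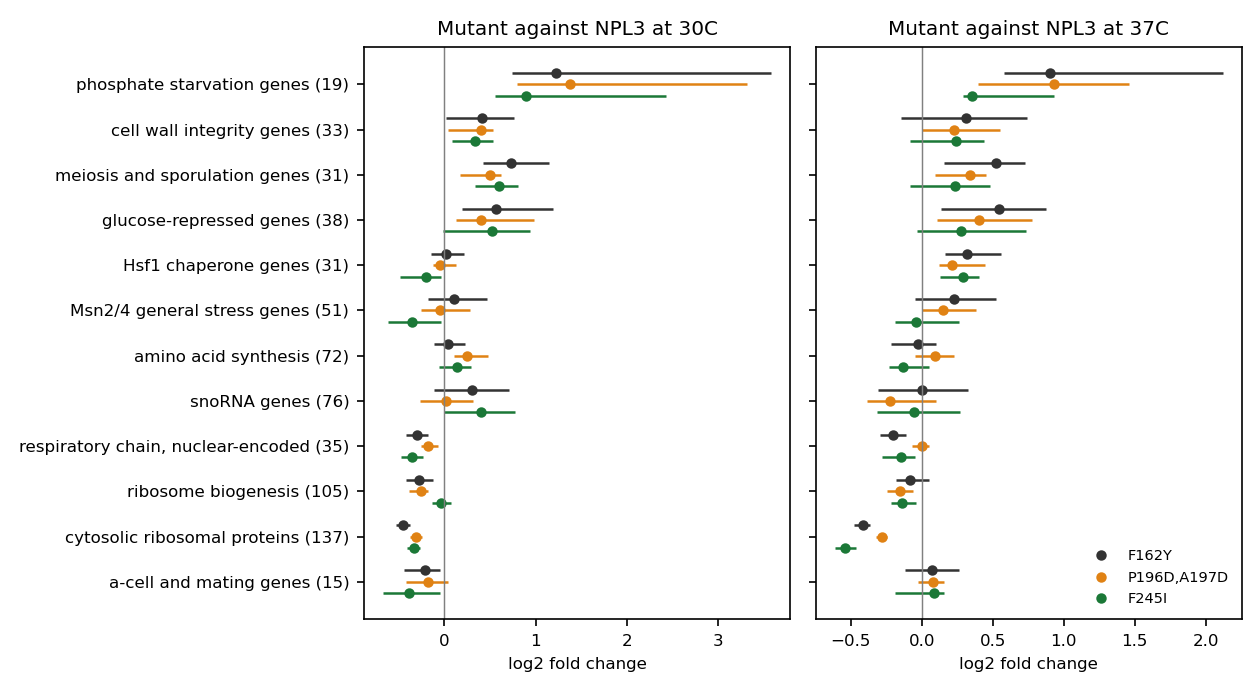
Median log2 fold change against NPL3 (horizontal axis) of 12 gene lists in the 3 mutants, at 30 °C and at 37 °C, with a dot for the median and a line from the lower to the upper quartile of the list's genes. Of the lists shown, phosphate starvation genes have the highest medians at 30 °C (1.22, 1.38 and 0.89), and ribosomal protein genes lie below 0 in all 6 comparisons (-0.28 to -0.54).

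The changes in the 3 mutants at 30 °C ran in the same direction. Of 2658 genes that passed in every mutant, 2621 (98.6%) changed the same way in all 3, 1507 of them lower. Independent lists of these sizes would share 114.3 higher and 265 lower genes, and simulated unchanged mutants against the same NPL3 libraries shared none in any of 20 simulations. That absence was fixed in advance, since hardly any gene passes when nothing is changed. It gives no value for the overlap of mutants that do change. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.904 for npl3-F162Y with npl3-P196D-A197D, 0.886 for npl3-F162Y with npl3-F245I and 0.831 for npl3-P196D-A197D with npl3-F245I, against 0.437, 0.486 and 0.465 in the simulations. The covariances were 0.241, 0.259 and 0.186, against simulated medians of 0.0169, 0.0163 and 0.0169. Part of the excess over independent lists may come from the shared NPL3 libraries, since 3 controls cannot be split into groups of 2 or more. The simulations share those libraries, so their values already hold the modelled spread between them (highest covariances 0.0209, 0.0214 and 0.0198). A difference of the NPL3 strain or its cultures would be shared by all mutants, and the simulations do not hold it.

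The next comparisons ask what the mutations change after 1 hour at 37 °C. In npl3-F162Y SPL2 rose 17.4-fold, PHO84 12.8-fold, SNO1 9.79-fold, SNZ1 6.32-fold, DPA10 10.3-fold and SPG4, named for survival in stationary phase, 10.1-fold (n = 3). OLE1, the fatty acid desaturase, fell from 1440 ± 221 to 511 ± 5.57 CPM and was 2.82-fold lower (adjusted p = 2.47e-14, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the largest falls were the glucanase genes SCW11 (2.31-fold lower) and DSE4 (2.26-fold lower), next to SLI1 (2.68-fold lower), the cleavage factor gene PTI1 (2.57-fold lower) and PRY1 (2.43-fold lower). Phosphate starvation genes rose in 18 of 19 cases, 19 adjusted over the list alone (camera adjusted p = 3.2e-34, adjusted p = 5.52e-06 with an estimated correlation). Ribosomal protein genes fell in 135 of 137 cases, 135 adjusted over the list alone, with a median of -0.42 (camera adjusted p = 9.87e-28, adjusted p = 0.35 with an estimated correlation). Of 31 Hsf1 chaperone genes 24 rose and none fell (camera adjusted p = 1.38e-05, adjusted p = 0.681 with an estimated correlation). The Hsp70 gene SSA3 rose 4.51-fold to 511 ± 27.1 CPM, and BTN2 rose 4.96-fold against an NPL3 level of 181 ± 94.7 CPM that varied between libraries. General stress genes rose in 26 of 51 cases, the transketolase gene TKL2 2.32-fold (camera adjusted p = 0.00411, adjusted p = 0.978 with an estimated correlation). In edgeR's test 3830 genes changed, 1822 higher and 2008 lower, and 3628 changed without replicate 2 of every group. When only these 6 libraries entered the fit 1462 were higher and 1321 lower.

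In npl3-P196D-A197D at 37 °C SPL2 rose 15.6-fold, PHO84 12.1-fold, SNO1 7.80-fold, DPA10 7.21-fold, PHO5 5.07-fold and SPG4 4.79-fold (n = 3). CHA1 was 2.68-fold lower, SLI1 2.77-fold lower, ULI1 2.09-fold lower, PTI1 2.08-fold lower, OLE1 2.03-fold lower and PRY1 1.93-fold lower. Phosphate starvation genes rose in 18 of 19 cases, 18 adjusted over the list alone (camera adjusted p = 5.8e-47, adjusted p = 4.42e-07 with an estimated correlation). Ribosomal protein genes fell in 129 of 137 cases with a median of -0.28, 131 adjusted over the list alone (camera adjusted p = 2.82e-23, adjusted p = 0.407 with an estimated correlation). Iron regulon genes rose in 18 of 28 cases, the siderophore-binding wall protein gene FIT2 1.85-fold (camera adjusted p = 0.00159, adjusted p = 0.152 with an estimated correlation). Amino acid synthesis genes rose in 33 of 72 cases, ARG1 1.82-fold and HIS4 1.61-fold (camera adjusted p = 0.00384, adjusted p = 0.79 with an estimated correlation). Hsf1 chaperone genes rose in 18 of 31 cases, SSA3 2.84-fold (camera adjusted p = 1.79e-05, adjusted p = 0.754 with an estimated correlation). The calls for GCD10 and TIF4631 ended without replicate 1 of NPL3 at 37 °C (adjusted p = 0.134 and 0.0695, edgeR). In edgeR's test 2850 genes changed, 1388 higher and 1462 lower, 2506 changed without replicate 2 of every group, and 1425 did when only these 6 libraries entered the fit, 850 higher and 575 lower.

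In npl3-F245I at 37 °C the phosphate genes stood less far above NPL3, with PHO84 up 5.85-fold, SPL2 5.80-fold and PHO5 4.06-fold (n = 3). SNO1 rose 6.86-fold and SNZ1 4.29-fold. NDC80, a kinetochore gene (chromosome IX, 78074 to 80149), rose 4.78-fold from 106 ± 3.89 to 506 ± 30.1 CPM (adjusted p = 5.24e-20, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CHA1 was 4.12-fold lower, the cell wall protein gene CWP1 2.56-fold lower, the aldehyde dehydrogenase gene ALD6 2.38-fold lower, OPT2 2.37-fold lower, the methionine synthase gene MET6 2.22-fold lower and NEJ1 2.05-fold lower. Of 72 amino acid synthesis genes 37 fell and 14 rose (camera adjusted p = 0.000728, adjusted p = 0.642 with an estimated correlation). Ribosomal protein genes fell in 136 of 137 cases, 136 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 2.11e-56, adjusted p = 0.15 with an estimated correlation), and RPL9A (chromosome VII, 227754 to 228329) was 1.87-fold lower. Phosphate starvation genes rose in 17 of 19 cases, 17 adjusted over the list alone (camera adjusted p = 1.05e-13, adjusted p = 0.00148 with an estimated correlation). Glycolysis genes fell in 11 of 17 cases, TDH1 1.57-fold lower and ENO1 1.42-fold lower (camera adjusted p = 0.0209, adjusted p = 0.857 with an estimated correlation). Glucose-repressed genes rose in 20 of 38 cases, the hexose transporter gene HXT5 2.49-fold (camera adjusted p = 0.000136, adjusted p = 0.218 with an estimated correlation). In edgeR's test 3295 genes changed, 1565 higher and 1730 lower, and 3090 changed without replicate 2 of every group. With only these 6 libraries in the fit 1179 were higher and 1098 lower.

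At 37 °C 1866 genes passed in all 3 mutants, and 1755 of them (94.1%) changed the same way, 862 higher and 893 lower. Independent lists would share 93.2 higher and 119.5 lower genes, and the 20 simulations shared none, which was fixed in advance here too. Across genes Pearson's r was 0.881 for npl3-F162Y with npl3-P196D-A197D, 0.738 for npl3-F162Y with npl3-F245I and 0.658 for npl3-P196D-A197D with npl3-F245I (simulated 0.466, 0.498 and 0.487). The covariances were 0.141, 0.130 and 0.0905 (simulated medians 0.0114, 0.0117 and 0.0116, highest 0.0122, 0.0152 and 0.0132). The shared NPL3 libraries may give part of the excess over independent lists. The excess over the simulations may hold a difference of the NPL3 strain or its cultures.

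The comparison of temperatures asks how cells with wild-type NPL3 respond to the shift. Chaperone and general stress genes rose. The small heat shock protein gene HSP26 went from 77.3 ± 2.82 to 1166 ± 138 CPM, 15.1-fold, and HSP12 rose 7-fold, the Hsp70 gene SSA4 4.87-fold, SHH3 9.56-fold, EGO4 7.12-fold and MOH1 6.36-fold (n = 3). HSP30 rose 12.6-fold to 198 ± 82.3 CPM. The glucose transporter gene HXT1 was 4.79-fold lower, HO 4.34-fold lower, the iron oxidase gene FET3 4.04-fold lower, NFG1 3.65-fold lower, the a-cell protease gene BAR1 3.61-fold lower and MFA2 3.25-fold lower. Of 51 general stress genes 46 rose, 47 adjusted over the list alone, with a median of 1.14 (camera adjusted p = 2.94e-35, adjusted p = 0.0661 with an estimated correlation). Of 31 Hsf1 chaperone genes 25 rose (camera adjusted p = 1.15e-14, adjusted p = 0.182 with an estimated correlation). Of 137 ribosomal protein genes 134 fell with a median of -0.75, 134 adjusted over the list alone, RPL9A 2.06-fold lower (camera adjusted p = 8.06e-56, adjusted p = 0.0661 with an estimated correlation).

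Many other groups moved with the shift in NPL3. Of 105 ribosome biogenesis genes 97 fell (camera adjusted p = 4.24e-08, adjusted p = 0.574 with an estimated correlation), and DBP2 fell to 208 ± 103 CPM from 605 ± 47.4 CPM. Of 41 translation factor genes 35 fell, the elongation factor gene YEF3 1.83-fold lower (camera adjusted p = 1.6e-11, adjusted p = 0.176 with an estimated correlation). Of 72 amino acid synthesis genes 60 fell (camera adjusted p = 1.64e-19, adjusted p = 0.0661 with an estimated correlation). Of 15 a-cell genes 12 fell (camera adjusted p = 1.13e-13, adjusted p = 0.00226 with an estimated correlation). Proteasome genes fell slightly but widely, 32 of 35, PRE2 1.35-fold lower (camera adjusted p = 3.8e-05, adjusted p = 0.182 with an estimated correlation). Nuclear exosome genes fell in 15 of 17 cases, RRP6 1.53-fold lower, and mRNP export genes in 22 of 34, the methyltransferase gene HMT1 1.57-fold lower (camera adjusted p = 0.00289 and 0.00981, adjusted p = 0.504 and 0.267 with an estimated correlation). Genes of RNA polymerase II and elongation fell in 21 of 29 cases (camera adjusted p = 0.0199, adjusted p = 0.357 with an estimated correlation). Glucose-repressed genes rose in 34 of 38 cases and DNA damage genes in 13 of 20 (camera adjusted p = 5.29e-09 and 0.024, adjusted p = 0.0661 and 0.103 with an estimated correlation). The rise of 17 of 33 cell wall integrity genes (camera adjusted p = 0.0294, adjusted p = 0.461 with an estimated correlation) did not pass without replicate 2 at 37 °C (adjusted p = 0.0552). In edgeR's quasi-likelihood test 4368 genes changed, 2223 higher and 2145 lower, and 4202 changed without replicate 2 of every group at 37 °C.

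The same shift was followed in each mutant. In npl3-F162Y 3998 genes changed (2239 higher and 1759 lower), in npl3-P196D-A197D 4032 (2175 and 1857) and in npl3-F245I 4472 (2462 and 2010), by edgeR's test. Without replicate 2 at 37 °C the counts were 3921, 3949 and 4409. General stress genes rose in 50, 50 and 51 of 51 cases (camera adjusted p = 1e-44, 2.03e-49 and 4.88e-44, adjusted p = 0.0511, 0.025 and 0.0416 with an estimated correlation). Hsf1 chaperone genes rose in 29 of 31 cases in each mutant (camera adjusted p = 1.41e-29, 5.87e-28 and 1.09e-28, adjusted p = 0.0511, 0.0509 and 0.042 with an estimated correlation), and HSP26 reached 2096 ± 90.4, 1770 ± 86.6 and 1199 ± 51.4 CPM (n = 3). Amino acid synthesis genes fell in 63, 63 and 66 of 72 cases (camera adjusted p = 1.29e-42, 2.21e-47 and 2.47e-48, adjusted p = 0.00884, 0.00601 and 0.00466 with an estimated correlation). Phosphate starvation genes fell in 13, 15 and 14 of 19 cases in the mutants (camera adjusted p = 8.59e-05, 5e-07 and 0.0031, adjusted p = 0.0511, 0.025 and 0.111 with an estimated correlation). In NPL3 9 of them rose and 3 fell, which did not pass (camera adjusted p = 0.0831).

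**Figure D3:**
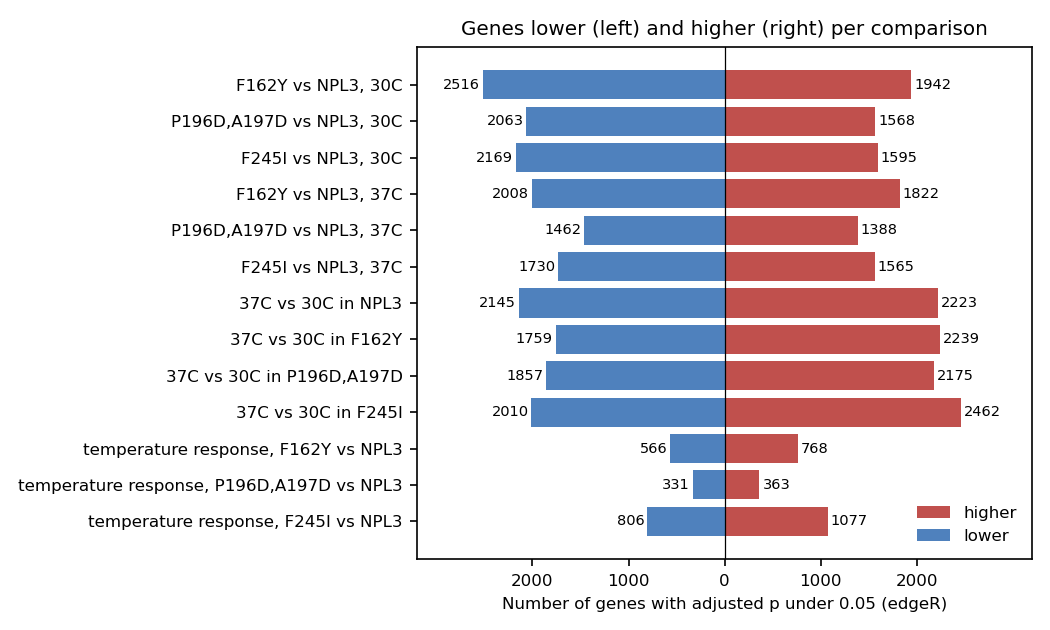
Number of genes past an adjusted p of 0.05 (horizontal axis) in 13 comparisons, with a bar to the left for genes that were lower and a bar to the right for genes that were higher. The bars for npl3-F162Y against NPL3 at 30 °C reach 2516 lower and 1942 higher genes, and the fewest genes, 694, differ in the temperature response of npl3-P196D-A197D.

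The difference between a mutant's and NPL3's response to the shift was tested as an interaction. A higher response can be a larger rise or a smaller fall. In npl3-F162Y the response of SSA3 was higher than in NPL3, with a log2 difference of 1.55 ± 0.0932 (SE). The responses of the a-factor gene MFA1 (1.36), RGM1 (1.16) and the transporter gene AQR1 (1.15) were also higher. MFA1 fell in both strains, from 145 to 49.9 CPM in NPL3 and from 113 to 99.5 CPM in npl3-F162Y. PHO5 (-2.09), PHO89 (-1.93), PHO11 (-1.77) and PHO12 (-1.67) lost ground to NPL3, the last pair near-identical in sequence. For PHO5 this was mostly a rise in NPL3, from 33.2 to 131 CPM, while npl3-F162Y went from 787 to 724 CPM. Of 19 phosphate starvation genes 12 had a lower response, 14 adjusted over the list alone (camera adjusted p = 4.62e-24, adjusted p = 3.11e-05 with an estimated correlation). Of 15 a-cell genes 10 had a higher response, 12 adjusted over the list alone (camera adjusted p = 1.86e-09, adjusted p = 0.00717 with an estimated correlation). Hsf1 chaperone genes had a higher response in 16 of 31 cases (camera adjusted p = 6.59e-10, adjusted p = 0.521 with an estimated correlation), and snoRNA genes a lower one in 17 of 76 (camera adjusted p = 5.74e-06, adjusted p = 0.514 with an estimated correlation). The interaction passed for 1334 genes in edgeR's test, 768 higher and 566 lower, and for 1152 without replicate 2 at 37 °C. The higher share was 57.6%, and 47.1% with RLE size factors. Without replicate 1 of NPL3 at 37 °C 1179 genes had a higher response.

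In npl3-P196D-A197D the response of HSP26 was higher by 1.51 ± 0.111 (log2, SE), that of TKL2 by 1.46, of SSA3 by 1.28 and of HO by 1.04. That of PHO5 differed by -2.22, of PHO11 by -2.10, of PHO12 by -2.02 and of PHO89 by -2.02. PHO5 went from 787 to 663 CPM in npl3-P196D-A197D, and from 33.2 to 131 CPM in NPL3. Phosphate starvation genes had a lower response in 13 of 19 cases and a-cell genes a higher one in 8 of 15, 14 and 8 adjusted over the list alone (camera adjusted p = 3.42e-47 and 1.28e-07, adjusted p = 3.98e-07 and 0.0185 with an estimated correlation). Amino acid synthesis genes had a lower response in 25 of 72 cases, 31 adjusted over the list alone (camera adjusted p = 1.98e-25, adjusted p = 0.0302 with an estimated correlation). Of 8 core histone genes 1 had a higher response (camera adjusted p = 0.0393, adjusted p = 0.827 with an estimated correlation). In edgeR's test 694 genes passed, 363 higher and 331 lower, and 630 did without replicate 2 at 37 °C. The higher responses were 52.3% of the 694 genes, and 43.0% with RLE size factors. With only the groups compared in the fit 309 passed (144 higher and 165 lower), and 1047 with the number series as a term, a setting chosen after the data were seen. This count moved with single NPL3 libraries: without replicate 1 at 37 °C 1275 genes passed, 774 higher and 501 lower, and without replicate 3 at 30 °C 235 passed as higher.

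In npl3-F245I the response of HXK1 was higher by 1.72 ± 0.220 (log2, SE), that of SSA3 by 1.43, of BTN2 by 1.28 and of the cyclin gene CLB6 by 1.14. That of OSI1 differed by -1.96, of DPA10 by -1.70, of PHO5 by -1.63 and of PHO89 by -1.57. PHO5 rose in both strains, from 419 to 530 CPM in npl3-F245I and from 33.2 to 131 CPM in NPL3. The NPL3 transcript had a higher response by 0.77 (adjusted p = 3.11e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 31 Hsf1 chaperone genes 26 had a higher response (camera adjusted p = 3.6e-15, adjusted p = 0.216 with an estimated correlation). Amino acid synthesis genes had a lower one in 45 of 72 cases and phosphate starvation genes in 15 of 19, 49 and 16 adjusted over the list alone (camera adjusted p = 2.35e-29 and 1.92e-16, adjusted p = 0.0237 and 0.000466 with an estimated correlation). Ribosomal protein genes fell further than in NPL3 in 69 of 137 cases (camera adjusted p = 5.29e-12, adjusted p = 0.522 with an estimated correlation), and respiratory chain genes had a higher response in 18 of 35 (camera adjusted p = 8.22e-05, adjusted p = 0.332 with an estimated correlation). In edgeR's test 1883 genes passed, 1077 higher and 806 lower, and 1944 did without replicate 2 at 37 °C. The higher responses were 57.2% of the 1883 genes, and 49.05% with RLE size factors.

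The mutants were also compared with each other, to ask which changes differ between them. With 1 allele per domain and 1 strain per allele, a difference cannot be assigned to the domain rather than the allele, strain or cultures. At 30 °C 1642 genes differed between npl3-P196D-A197D and npl3-F162Y (918 higher in the former and 724 lower), 2199 between npl3-F245I and npl3-F162Y (1096 and 1103), and 1839 between npl3-P196D-A197D and npl3-F245I (1083 and 756), by edgeR's test. With only the 6 libraries compared in the fit these were 2571, 3339 and 2792 genes. The phosphate starvation genes were lower in npl3-F245I than in npl3-F162Y in 14 of 19 cases (camera adjusted p = 5.58e-29, adjusted p = 4.85e-06 with an estimated correlation) and higher in npl3-P196D-A197D than in npl3-F245I in 16 (camera adjusted p = 2.66e-29, adjusted p = 6.72e-06 with an estimated correlation). General stress genes were lower in npl3-F245I than in npl3-F162Y in 42 of 51 cases, HSP12 2.33-fold lower and TKL2 2.44-fold lower (camera adjusted p = 1.18e-19, adjusted p = 0.306 with an estimated correlation). Amino acid synthesis genes were higher in npl3-P196D-A197D than in npl3-F162Y in 51 of 72 cases (camera adjusted p = 7.36e-24, adjusted p = 0.0943 with an estimated correlation). HXK1 stood 2.61-fold, RTC3 2.59-fold and AAD4 2.39-fold higher in npl3-P196D-A197D than in npl3-F245I, and LSM4, of an RNA decay complex, was 1.76-fold lower. Between npl3-F245I and npl3-F162Y the call for BSC1 ended without replicate 3 of npl3-F162Y (adjusted p = 0.0506, edgeR), and 694 genes were higher without replicate 3 of npl3-F245I.

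At 37 °C 1257 genes differed between npl3-P196D-A197D and npl3-F162Y (675 higher and 582 lower), 2490 between npl3-F245I and npl3-F162Y (1208 and 1282), and 2455 between npl3-P196D-A197D and npl3-F245I (1346 and 1109). Without replicate 2 the counts were 1244, 2366 and 2255, and without replicate 1 of npl3-F162Y 433 genes were higher in npl3-P196D-A197D. OLE1 was 2.65-fold and DSE2 2.11-fold higher in npl3-F245I than in npl3-F162Y, and the carbonic anhydrase gene NCE103 was 3.13-fold lower and DPA10 3.38-fold lower. OSI1 was 3.92-fold, AAD4 3.29-fold and the NADPH oxidoreductase gene OYE3 2.78-fold higher in npl3-P196D-A197D than in npl3-F245I. FLO11, a cell-surface flocculin gene, was 2.23-fold lower and HMS1 2.94-fold lower. Ribosomal protein genes were higher in npl3-P196D-A197D than in npl3-F245I in 122 of 137 cases (camera adjusted p = 9.5e-19, adjusted p = 0.693 with an estimated correlation). PHO89 was 2.12-fold lower and SPG4 2.10-fold lower in npl3-P196D-A197D than in npl3-F162Y, where GTT2, a glutathione transferase gene, was 1.66-fold higher in the linker mutant.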

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

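The tests of gene length and abundance, of snoRNA genes and of other splits of the libraries were set before their own values were computed. Those of ribosomal protein and snoRNA genes address patterns that the list results had already shown. The remaining tests were chosen after the results had been seen. What set the temperature responses apart was a difference between groups, since the interaction test passed for 1334 genes in npl3-F162Y, 694 in npl3-P196D-A197D and 1883 in npl3-F245I. In npl3-F162Y the log2 differences from the response of NPL3 were 1.55 for SSA3, 1.36 for MFA1, 1.16 for RGM1, 1.15 for AQR1, -2.09 for PHO5, -1.93 for PHO89, -1.77 for PHO11 and -1.67 for PHO12. In npl3-P196D-A197D they were 1.51 for HSP26, 1.46 for TKL2, 1.28 for SSA3, 1.04 for HO, -2.22 for PHO5, -2.10 for PHO11, -2.02 for PHO12 and -2.02 for PHO89. In npl3-F245I they were 1.72 for HXK1, 1.43 for SSA3, 1.28 for BTN2, 1.14 for CLB6, 0.77 for NPL3, -1.96 for OSI1, -1.70 for DPA10, -1.63 for PHO5 and -1.57 for PHO89. The median differences of the lists were 0.38 for a-cell genes and -0.32 for phosphate starvation genes in npl3-F162Y, 0.26, -0.45 and, for amino acid synthesis, -0.14 in npl3-P196D-A197D, and 0.36, -0.44 and -0.27 in npl3-F245I. In npl3-F245I the strain marker list also passed, with a median of -0.10 (adjusted p = 0.0276 with an estimated correlation in limma's camera), but its members were mixed. With the shift LEU2 went from 314 to 165 CPM in npl3-F245I and from 289 to 311 CPM in NPL3. CAN1 went the other way, falling less in npl3-F245I (155 to 144 CPM) than in NPL3 (166 to 142 CPM).

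Other splits of the 12 libraries in each interaction cannot decide for or against chance by their share. As many genes as in the real split, itself included, were reached in 10 of 100 splits in npl3-F162Y (1334 genes, highest other 4783), 16 in npl3-P196D-A197D (694, highest other 3147) and 6 in npl3-F245I (1883, highest other 3128). Every split with several times the real count exchanged unequal numbers of libraries between strains at 30 °C and 37 °C. Such exchange moves the effect of the allele into the interaction, so neither these counts nor the shares measure chance. Splits that exchanged equally many libraries between strains at both temperatures gave no gene (highest 0 over 38, 36 and 41 splits by edgeR), while unequal exchange places part of the effect of the allele into the interaction. Any exchange also puts the effect of the allele into the spread within groups. A count near 0 after equal exchange therefore follows with or without an interaction. With a difference of 1 exchanged library splits gave up to 1631, 2001 and 1399 genes, and 2, 7 and 0 of them as many as the real split. With a difference of 2 they gave up to 3787, 3147 and 3128 genes (6 of 6, 8 of 8 and 5 of 10 as many), and the 1 split with a difference of 3, in npl3-F162Y, gave 4783. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, with 1 split, the real one, at the real count in each. The highest other splits gave 98 genes in npl3-F162Y at 37 °C (3830 real), 211 in npl3-P196D-A197D at 37 °C (2850 real), 201 in the shift of NPL3 (4368 real), 51 between npl3-P196D-A197D and npl3-F162Y at 37 °C (1257 real) and 15 between npl3-P196D-A197D and npl3-F245I at 37 °C (2455 real). In the remaining comparisons the highest other split gave 0 genes. Mixed groups widen the spread here too, so these low counts do not measure chance. Same-numbered libraries of npl3-F162Y and NPL3 at 37 °C deviated together, though some with unlike numbers did too, and there the 3 other splits that part all pairs gave 0 genes and the 6 that part 1 pair gave up to 98.

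The phosphate starvation genes stood higher in all 3 mutants. Reads shared between near-identical genes could not explain this, since the smallest of the mutant medians at 30 °C over members without such a copy was 0.82. An error in the NPL3 libraries at 30 °C alone was argued against by the smallest median at 37 °C, 0.35, and a shared difference of the NPL3 strain as the whole change by 14 of 19 members that differed between npl3-F245I and npl3-F162Y at 30 °C. With 1 strain per allele, the part that the mutants share (smallest median 0.89) cannot be told apart from a difference of the NPL3 strain or its cultures.

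The ribosomal protein genes stood lower in all 3 mutants, a list call that was lost with an estimated correlation in all 6 comparisons (camera adjusted p = 0.477, 0.499 and 0.455 at 30 °C and adjusted p = 0.35, 0.407 and 0.15 at 37 °C). Against the genes nearest in length, abundance and GC content the difference nearest to 0 of the 6 comparisons was -0.24. These genes were matched only in part, with a median of 437 CPM against 727 CPM and of 522 bases against 432 bases. Against all genes, as a check of the scaling, the difference was -0.27. In npl3-F245I at 30 °C the Msn2 and Msn4 genes had a median of -0.36, which argues against a rise of this regulon behind the lower values there. This check was chosen after that median had been seen. It covers no other comparison and no stress response outside this regulon.

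Of 76 snoRNA genes 41 rose and 8 fell in npl3-F162Y at 30 °C, and 39 rose and 5 fell in npl3-F245I, list calls that were lost with an estimated correlation (camera adjusted p = 0.743 and 0.455). Over the 65 that overlap no other gene the smaller of both medians was 0.45, so reads of an overlapping gene could not explain the higher values of these 65. The libraries were prepared with an mRNA kit, and snoRNA genes held 0.0621 to 0.1001% of the assigned counts. Whether the values show the level of mature snoRNAs was not tested. Whether transcripts run on from an upstream gene stays open, since snoRNA genes near an upstream gene on the same strand differed from the others by 0.12 in npl3-F162Y (95% interval -0.19 to 0.46). Reads in no feature set the mutants apart at 30 °C as a signal in data outside the genes, with 5.18 ± 0.075% in npl3-F162Y, 4.90 ± 0.219% in npl3-P196D-A197D and 5.08 ± 0.255% in npl3-F245I against 4.53 ± 0.125% in NPL3 (SD, n = 3). The lowest npl3-P196D-A197D library, at 4.649%, was hardly above the highest NPL3 library, at 4.626%, and no test was run. At 37 °C reads in no feature did not set the mutants apart, with 6.21%, 5.70% and 5.66% against 5.72%, and the SD was up to 0.521.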

How the results depend on the processing

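The title number series as a term was an alternative chosen after the result was seen, and the others were set before the data were examined. The counts of all 19 comparisons stayed within 1.5 times under RLE size factors, DESeq2, both filters and without the 4 libraries of the other number series, and no named gene or called list reversed. Which direction held more of the interaction calls depended on the scaling, since higher responses were 57.57, 52.31 and 57.2% of them in npl3-F162Y, npl3-P196D-A197D and npl3-F245I, and 47.06, 42.96 and 49.05% with RLE size factors. Replicate number was also used as a block, although the numbers did not pair the libraries throughout. With it 4514, 3704 and 3851 genes changed at 30 °C and 3896, 2965 and 3401 at 37 °C in npl3-F162Y, npl3-P196D-A197D and npl3-F245I. With that block 198 of 201 list calls held. It ended those of the iron regulon (adjusted p = 0.0503) and ribosome biogenesis (adjusted p = 0.0505) in npl3-F162Y at 30 °C and of snoRNA genes in the shift of npl3-F245I (adjusted p = 0.0543, camera), and it changed no other call among the named genes. As a block within each temperature it gave 575 genes with a higher response in npl3-P196D-A197D (363 without it). With an estimated correlation 33 of the 201 list calls held. A fit of only the groups compared has fewer samples and takes the spread from these groups alone. In it 1425 genes changed in npl3-P196D-A197D at 37 °C and 309 had another temperature response. More genes than in the main fit, 2571, 3339 and 2792, differed between mutants at 30 °C (npl3-P196D-A197D and npl3-F162Y, npl3-F245I and npl3-F162Y, npl3-P196D-A197D and npl3-F245I). The spread between replicates was unequal. Over genes, the chi-square per degree of freedom between 2 replicates was 25.3 to 58.2 in NPL3 at 37 °C and 2.77 to 4.77 in the mutants at 30 °C. The main fit shares 1 estimate of the spread per gene, so its counts against NPL3 at 37 °C may be too high. The interaction of npl3-P196D-A197D passed for 1047 genes with the number series as a term and for 499 to 1275 with 1 library left out, the highest without replicate 1 of NPL3 at 37 °C, and the cause was not tested. With 1 library left out, 4100 to 4245, 3199 to 3433 and 3319 to 3534 genes changed at 30 °C, 3450 to 3840, 2424 to 3106 and 2939 to 3378 at 37 °C, and 1083 to 1933 and 1608 to 2078 had another temperature response in npl3-F162Y and npl3-F245I. At a change of at least 2-fold 168 genes were shared by the mutants at 30 °C and 73 at 37 °C, which follows from fewer genes passing. Of 2070 results for named genes with 1 library left out 2066 held. The naming rule picked mostly large changes that passed in these same data, so that share was largely fixed. It says little about smaller calls. At this depth 80% of genes planted at the smallest simulated fold were recovered in npl3-F162Y at 30 °C, and 58% in its interaction.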

Other observations

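The 3 lists described here were chosen after the data were seen, and the test of downstream genes was set before. Genes of vitamins B6 and B1 rose in 11 of 18 cases in each mutant at 30 °C (adjusted p = 0.00775, 0.00388 and 0.00586 with an estimated correlation in limma's camera), and SNZ1, set out here after its values were seen, stood at 486 ± 19.6, 374 ± 14.1 and 401 ± 5.54 CPM against 39.3 ± 0.957 in NPL3 (SD, n = 3).

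Sulfate assimilation and methionine genes rose in 15 of 25 cases in npl3-P196D-A197D at 30 °C (adjusted p = 0.000362 with an estimated correlation in camera). At 37 °C they fell in 16 cases in npl3-F162Y and in 20 in npl3-F245I (adjusted p = 0.00581 and 6.22e-05 with an estimated correlation in camera). Zinc genes of the Zap1 regulon passed in npl3-F245I at 30 °C, 4 of 9 higher (camera adjusted p = 0.00834, adjusted p = 0.068 with an estimated correlation), and did not pass in the other mutants there (camera adjusted p = 0.21 and 0.13). ZRT1, a zinc transporter gene chosen after its values were seen, rose by 2.02, 1.77 and 2.05 on the log2 scale at 30 °C. NDC80, also chosen after its values were seen, rose by 2.10, 1.29 and 1.96 at 30 °C. LEU2, the plasmid marker chosen after its values were seen, stood at 311 ± 8.68 CPM in NPL3, 214 ± 10.4 in npl3-F162Y, 379 ± 10.7 in npl3-P196D-A197D and 165 ± 4.79 in npl3-F245I at 37 °C (SD, n = 3), where the NPL3 transcript stood higher in each mutant. At 30 °C LEU2 stood at 289 ± 8.16, 253 ± 6.47, 384 ± 19.7 and 314 ± 2.81 CPM.

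Transcripts that run on past their end in the mutants could raise genes that lie downstream on the same strand. Weakly expressed genes with a same-strand neighbour upstream (81 genes) differed from those with an other-strand neighbour (112 genes) by -0.0546 in npl3-F162Y at 30 °C (95% interval -0.38 to 0.42), 0.08 in npl3-P196D-A197D and -0.04 in npl3-F245I. The interval is wide, and the hypothesis stays open.

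As a value that belongs to no comparison, 1448 genes passed edgeR's test for the sample number series of 4 libraries, 632 higher and 816 lower.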
